A study of Mus musculus with 4 samples.

How the data were processed

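Whole-genome bisulfite sequencing libraries of mouse bone marrow erythroblasts were analysed, 1 library for each combination of genotype (wild type or Bach1 knockout) and diet (normal or low iron), 4 libraries in all. Cells were sorted on CD71 and Ter119, DNA was purified with a QIAamp kit, and libraries were made by post-bisulfite adaptor tagging and sequenced on an Illumina HiSeq instrument, per the labels' protocols. Reads were processed with Bismark against mm10, per the submitters' processing notes; the Bismark version, read trimming and duplicate removal are not given in the sources used here. For each cytosine the deposited coverage files give the counts of methylated and unmethylated calls, which the authors made from their alignments, and the deposited percent of methylated calls, which equalled the ratio of those counts in every file. All values below were computed from the counts. Adjacent listed positions were taken as the plus and minus strand cytosines of a CpG; runs of odd length were given no strand.

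The files held 20728228, 16709175, 15632353 and 15026503 cytosines for the wild-type normal-diet, wild-type low-iron, knockout normal-diet and knockout low-iron libraries, with a median of 3 calls each. They covered 12, 11, 10 and 9 chromosomes, and only chromosomes 11 and 17 were analysed in all 4 libraries, with 13393599, 13513748, 13379287 and 14233531 calls. Each main comparison was made on those chromosomes. Results on all chromosomes shared by a pair of libraries were added after seeing the data, and gene lists were measured on them because chromosomes 11 and 17 hold few members. Chromosome X and mitochondrial DNA were not analysed here.

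Methylation levels are methylated calls over all calls. Intervals for levels are 95% Wilson intervals and cover counting error only. Calls were summed over 2000-bp tiles with at least 4 covered CpGs and 20 calls in each of the 4 libraries, and over promoter windows with at least 5 CpGs and 20 calls. A region was called at a Benjamini-Hochberg adjusted p below 0.05 in a two-sided Fisher's exact test and a difference of at least 20 percentage points. The difference of the diet differences used a z statistic after adding 1 methylated and 1 unmethylated call to each library and a minimum of 30 points. With 1 library per group these tests compare libraries. The 4 comparisons were the diet within each genotype and the genotype within each diet, always the first library named minus the second.

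Some steps of the fixed design were changed because the gene table used (GRCm38.p6, the assembly of mm10) gives gene starts and ends without strand, and no genome sequence was used. The transcription start was replaced by the gene end with at least 1.5 times the CpGs of the other within 1000 bp, and genes of at most 2000 bp were taken whole with 1000 bp on each side. Of 18883 protein-coding genes, 13444 had such an end, 1976 were short and 3463 had none and were left out. On chromosomes 11 and 17, 76.0% of richer ends were under 20% methylated against 4.10% of the other ends (1904 genes), so the window is called a promoter here but need not hold the transcription start of each gene. CpG islands were replaced by 500-bp windows with at least 25 CpGs. Exons, introns and windows around BACH1 binding motifs were not analysed here.

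The 15 gene lists were globin genes, heme synthesis, iron handling, BACH1 and NRF2 targets, erythroid factors and red cell membrane, the heme-regulated kinase and ATF4 pathway, DNA methylation enzymes, imprinted, germline and housekeeping promoters, and markers of myeloid, B, T and NK, megakaryocyte, and stem and progenitor cells. The lists, tests, thresholds and other settings were fixed before the data were examined, apart from those said to be added or changed. The median difference of a list with at least 3 measured members was placed as a percentile among 10000 random lists of the same size matched on level in 10 bins, as a description only. Members were counted as called over all promoters and adjusted over the list alone. Whole gene spans with 1000 bp on each side were added after seeing the data. Named genes were the 8 called promoters with the largest rise and the 8 with the largest fall, leaving out predicted genes and families of near-identical copies, and list members that were called or, failing that, the 2 with the largest absolute difference, of which those of at least 5 points are given. That rule was fixed beforehand, but the name patterns that put it into effect were written after the data were seen, and they did not catch Tgtp2, Zfp980, Pramel18 and AAdacl4fm3, which have similar copies and were kept as uncertain. Tiles were named by their p after the values were seen.

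The other settings were coverage minimums of 40 and 10 calls, minimum differences of 30 points (40 for the difference of differences), tiles of 1 and 5 kb, promoter windows of 500 bp on each side or 2000 bp outside the end, testing against the median difference, dividing z by the root of its inflation, thinning to the shallowest library, and leaving out cytosines above the 99.9 percentile of calls (more than 16 or 17 calls). For the level, cytosines called in all 4 libraries, cytosines with at least 5 calls and the mean of their levels were used. The comparison of plus and minus strands within a library was added after seeing the data, and its mean inflation of 1.82 served as a further setting. It lay above the inflation of the wild-type diet and normal-diet genotype comparisons on 1 strand (1.64 to 1.68).

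The tile test was tested on simulated data made from the depths of the knockout and wild-type normal-diet libraries over 93927 tiles with 200 changed. With independent calls it recovered 19.5% of changes of 20 points, 63.0% of 30 points and 83.5% of 40 points, with 2, 2 and 4 unchanged tiles called. With no change, it called 0 tiles when calls were independent and 69 when calls within a tile were correlated (inflation 1.61). Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, with random seed 1.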

Results

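DNA methylation at CpG sites was measured by whole-genome bisulfite sequencing in mouse erythroblasts, the nucleated precursors of red blood cells. The cells were bone marrow cells of C57BL/6 mice sorted as high for CD71, the transferrin receptor, and positive for the red cell marker Ter119. The 4 libraries cross genotype with diet: wild type and Bach1 knockout, each on a normal diet or on a low iron diet given for 7 weeks from weaning at 3 weeks. BACH1 is a transcriptional repressor that binds heme, and the design asks how erythroblasts respond to iron shortage with and without it. Each group holds 1 library, so every test on reads below compares 2 libraries, not 2 conditions, and no difference has a replicate check. All deposited calls given for each library numbered 77087448 in the wild-type normal-diet library, 63229466 in the wild-type low-iron library, 59165704 in the knockout normal-diet library and 60774584 in the knockout low-iron library, and only part of them entered a comparison. The mean depth was 3.72, 3.78, 3.78 and 4.04 calls per cytosine, in the same order. Chromosomes 11 and 17 were analysed in all 4 libraries and carry the comparisons, while other chromosomes were used only where both libraries of a pair held them. All intervals are 95% Wilson intervals for single levels and normal intervals for differences, and they cover counting error only. With 1 library per group they hold no variation between animals or libraries. They also treat calls as independent, and whether duplicate reads were removed is not given in the sources used here.

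The targeted gene was examined first. Bach1 spans 87698954 to 87733346 on chromosome 16 (mm10), which was analysed in 3 libraries; chromosome 16 of the knockout normal-diet library was not analysed here, so the genotype label of that library has no such check. Calls per CpG over the gene, relative to the mean of each library, were 1.12 in the wild-type normal-diet library, 1.11 in the wild-type low-iron library and 1.0 in the knockout low-iron library, so the gene as a whole was covered in the knockout library. Inside the gene, a stretch of 239 bp from 87715334 to 87715572 with 17 cytosines held 150 calls in the wild-type normal-diet library, 50 in the wild-type low-iron library and 0 in the knockout low-iron library. Among 66557 stretches of the chromosome chosen in the same way it ranked 1 by the calls of both wild-type libraries, but 11 by those of the low-iron library alone. In the 500 bp above this stretch the methylation level was 81.6% (95% interval 73.9 to 87.4) and 76.7% (66.8 to 84.4) in the wild-type normal-diet and low-iron libraries, and 9.52% (5.26 to 16.6) in the knockout library. The 500 bp below it differed little, at 82.2%, 81.0% and 77.5% (67.8 to 85.0) in the same order. A 2-kb tile of Bach1 at 87726001 to 87728000 was 30.5% and 36.6% methylated in wild type and 70.5% in the knockout library, a rise of 37.2 points over the pooled wild-type level (two-sided Fisher's exact test, p = 7.10e-34, adjusted p = 2.88e-29 over 40607 tiles). The tile at 87714001 to 87716000 lay 25.1 points lower in the knockout library, at 55.2% (difference -25.1, p = 4.30e-15 by the same exact test).

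**Figure D1:**
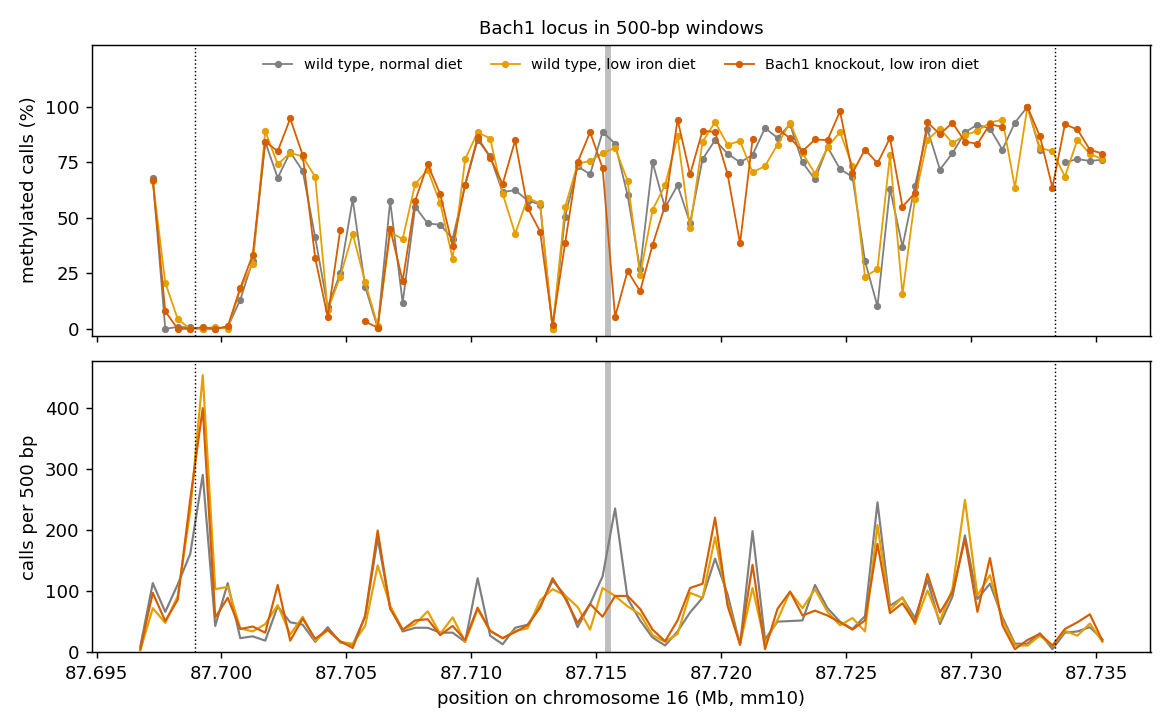
Methylation level in percent (upper panel, windows with at least 10 calls) and calls per 500 bp (lower panel) along chromosome 16 around Bach1, whose ends are the dotted lines, in the 3 libraries that hold the chromosome. The grey band marks the 239-bp stretch with 0 calls in the knockout low-iron library; just above it that library lies at 9.52% over 500 bp and the wild-type libraries at 81.6% and 76.7%.

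Across chromosomes 11 and 17 the methylation level was 49.8% in the wild-type normal-diet library, 49.4% in the wild-type low-iron library, 49.9% in the knockout normal-diet library and 53.9% in the knockout low-iron library, with counting intervals narrower than the last digit printed. Gene spans outside the promoter windows lay at 56.6%, 56.3%, 56.2% and 60.6% in that order, and sequence outside protein-coding genes at 48.3%, 47.5%, 47.9% and 52.4%. Promoter windows, taken as the CpG-richer end of each gene, lay at 12.5%, 13.0%, 13.9% and 14.2%. CpG-dense 500-bp windows lay at 9.91%, 9.66%, 11.1% and 10.6%, so the knockout low-iron library was below the knockout normal-diet library there. The knockout normal-diet library held 1083554 calls in these dense windows, against 1267121 to 1313601 in the others. In promoter windows it held 874445, against 985737 to 1024118. Over all cytosines it held 13379287, close to the 13393599 of the wild-type normal-diet library. Levels pool calls, so they can shift with where calls lie. How far this moved levels and differences of that library was not tested.

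**Figure D2:**
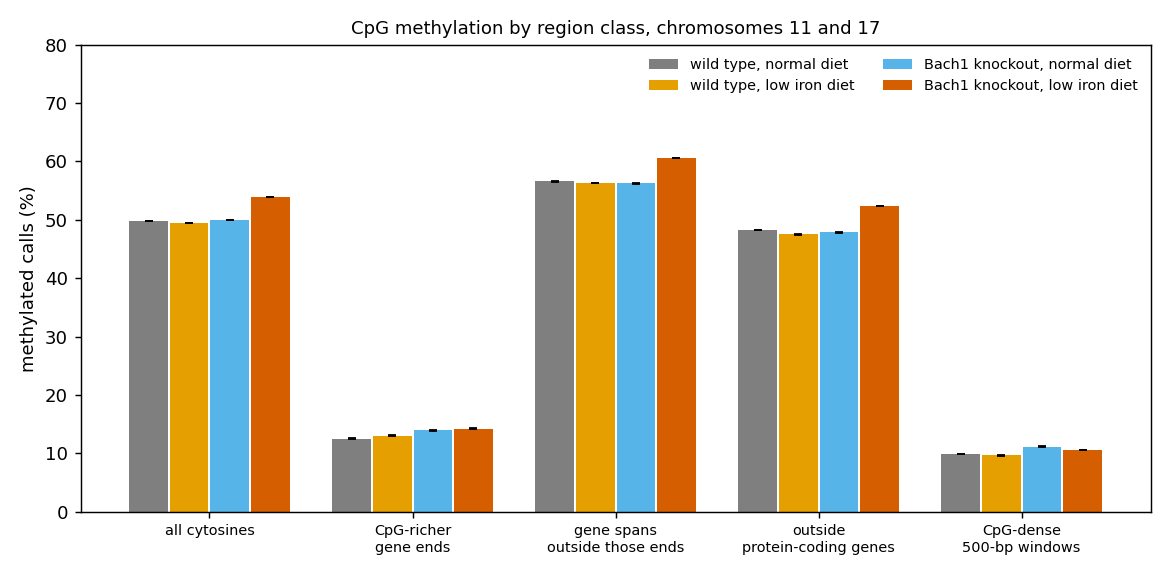
Percent of methylated calls per region class on chromosomes 11 and 17, 1 bar per library, with 95% Wilson intervals that are narrower than the bar outlines. The knockout low-iron library stands highest over gene spans (60.6%) and outside genes (52.4%), and the 4 libraries lie between 9.66% and 11.1% in CpG-dense windows.

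The first comparison asks what the low iron diet went with in wild-type erythroblasts. Methylation was slightly lower in the low-iron library, by -0.370 points on chromosomes 11 and 17 (95% interval -0.408 to -0.332), and lower on 9 of 9 shared chromosomes (-0.741 to -0.182). Among named promoters, that of Myo1f, a myosin motor of immune cells, fell from 67.9% to 47.6% (difference -20.3 points, adjusted p = 0.0367, Fisher's exact test). On the other shared chromosomes the promoter of Kbtbd6, an adaptor of a ubiquitin ligase, rose from 16.5% to 41.1% (24.6 points, adjusted p = 3.96e-06, exact test). The promoter of Edar, the ectodysplasin receptor, fell from 40.7% to 19.9% (-20.8 points, adjusted p = 7.85e-06, exact test). Cd200r2, of the CD200 receptor family, rose by 28.6 points and Crisp4, a secreted protein of the male tract, fell by 32.7 points, on 30 to 70 calls per library. Of these only Myo1f kept its call in both other windows: with 500 bp on each side Kbtbd6 stood at 1.14 points and Crisp4 at -18.4, and with 2 kb outside the end Edar stood at -10.9 and Cd200r2 at 18.7, none of them called. Of 2159 promoters tested on chromosomes 11 and 17, 3 were called, 2 higher and 1 lower; the higher pair, olfactory receptor genes Olfr56 (20.7 points) and Olfr20 (30.4), lies outside the naming rule and was named after the values were seen. Of 93927 tiles, 236 were called, 95 higher and 141 lower. The tiles with the smallest p, named after their values were seen, included one in Plekhh2 (69.6% to 35.3%), one in Kcnh6, a potassium channel gene (21.8% to 60.5%), and one in Grm4, a glutamate receptor gene (67.5% to 42.5%). As a rough background, the plus and minus strands of the same library were compared in the same way: 547 to 693 of 67984 tiles were called between strands, against 250 and 263 between these 2 libraries on 1 strand. The inflation between strands (1.79 to 1.85) lay above that between these libraries on 1 strand (1.64 and 1.68). The strand comparison thus holds more than calls that are not independent, and is not a clean background. Scaling the test by the inflation of its own statistics left 3 tiles and 0 promoters.

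Promoters of the pathways linked to iron and heme differed little between the wild-type libraries, and 0 members of any list were called over all promoters or adjusted over the list alone in this comparison. The 10 measured iron handling promoters had a median difference of 0.648 points, at the 77.6 percentile of 10000 random lists matched on level. Slc11a2, the iron importer DMT1, lay at 4.59% and 8.61%, and Tfrc, the transferrin receptor, at 1.84% and 2.15%, on the normal and low iron diets. The heme synthesis list (4 promoters) had a median of 1.10 points (percentile 82.0), with Slc25a37, the mitochondrial iron importer mitoferrin, 10.4 points higher and Tmem14c, a porphyrin transporter, at -9.61 points. The BACH1 and NRF2 target list (5 promoters) had a median of 0.639 (63.1), where Slc48a1, a heme transporter, lay at 4.99% and 10.6% (adjusted p = 0.0125, exact test, under the 20-point minimum). Medians of the erythroid factor and membrane list (7 promoters, -0.606, percentile 4.72), the heme-regulated kinase and ATF4 list (5, -0.0221, 38.1), the methylation enzyme list (6, -0.408, 18.6) and the globin list (5, 0.498, 54.4) were also under 1 point, though single members lay further apart: Hba-a2 at 15.3% and 33.3%, on 72 and 54 calls, Hbq1a at 32.8% and 24.4%, and Dnmt3a, a DNA methyltransferase, at 62.8% and 52.6%. Slc39a14, a metal importer of the iron handling list, lay at 6.49% and 12.4%. Among marker lists of other cell types, the myeloid median was -5.39 points (5 promoters, percentile 3.92), the stem and progenitor median 1.97 (6, 97.1), the B cell median 2.16 (3, 87.2) and the T and NK cell median -1.45 (3, 8.44). Several of these placements moved with the window: with 500 bp on each side the erythroid list stood at percentile 71.1 and the stem and progenitor list at 46.6, and with 2 kb outside the end the myeloid list stood at 40.8, the BACH1 and NRF2 target list at 25.6 and the housekeeping list at 24.0. Of the myeloid members, Fcgr3, an immunoglobulin receptor, lay at 12.3% and 6.69% (adjusted p = 0.000171, exact test, again under the minimum), and Prtn3, a neutrophil protease, at 37.7% and 28.7%. Of the stem and progenitor members Slamf1 lay 12.3 points higher and Cd34 at 7.84% and 13.0%, and the 2 measured megakaryocyte promoters, Itgb3 and Selp, differed by -6.43 and -5.63 points. The median difference was 0.391 points for housekeeping promoters (5, percentile 66.3) and 0.398 for germline promoters (5, 64.2). The germline members went both ways, 3 higher and 2 lower, and Dazl, a germ cell gene, lay at 47.5% and 59.7% (12.2 points, adjusted p = 3.94e-05, exact test, under the 20-point minimum). Of the imprinted promoters 2 were measured, 1 higher and 1 lower, with Zrsr1 at 55.1% and 51.8%. These percentiles describe these libraries and are not tests.

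The second comparison asks the same of the diet in the absence of BACH1. Methylation was higher in the knockout low-iron library by 3.96 points (95% interval 3.92 to 4.0) on chromosomes 11 and 17, and higher on 4 of 4 shared chromosomes (3.95 to 4.60). The difference depended on the starting level. Tiles under 5% methylated in wild type differed by 0.050 points (-0.0120 to 0.112), tiles at 10 to 20% by -0.923 points (-1.04 to -0.801), tiles at 50 to 60% by 5.56 points (5.49 to 5.64) and tiles at 80 to 90% by 2.53 points (2.37 to 2.69). Over 500-kb windows, 363 of 364 were higher. The promoter window shared by Evi2 and Evi2a, genes at a viral integration site inside Nf1, rose from 27.3% to 50% (22.7 points, adjusted p = 0.00515, Fisher's exact test). Promoters of Smim23 (22.6 points), Tdrd6, a tudor protein of male germ cells (22.4), and Cd300c2, a receptor of myeloid cells (22.2), rose as well. The promoter of Tgtp2, an interferon-induced GTPase, fell from 43.5% to 8.62% (-34.9 points, adjusted p = 0.00304, exact test), on 46 and 58 calls and with a near-identical gene copy, which leaves it uncertain. These calls depended on the window. With 500 bp on each side Tgtp2 differed by 0 points, Evi2 and Evi2a by 10.7 and Tdrd6 by 14.8, with 2 kb outside the end they stood at -16.6, 21.2 and 15.2, and these 4 and Smim23 were called in neither, while Cd300c2 was called in both. On chromosome 4, promoters of Zfp980 (26.6 points), Pramel18 (26.1) and AAdacl4fm3 (29.1), each of a family with similar copies, rose; none was called with 500 bp on each side (27.2, 14.9 and 19.3 points).

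Of 2159 promoters, 13 were called between the knockout libraries, 12 higher and 1 lower, with the window shared by Evi2 and Evi2a counted for each gene. Among those outside the naming rule, named after its values were seen, the olfactory receptor gene Olfr10 rose from 34.6% to 65.3%. Of 93927 tiles, 1489 were called, 1415 higher and 74 lower. Tested against the median tile difference of 4.76 points, 737 tiles were called, 407 higher and 330 lower, a split that the centring itself evens out. Scaling by the inflation of the statistics left 6 tiles and 0 promoters, and scaling by the inflation between strands left 30 tiles. The first inflation comes from the same uncentred statistics, so it counts a shift of the whole library as noise and removes calls partly by construction. On 1 strand it was 2.10 and 2.09 here, against 1.64 and 1.68 between the wild-type libraries. Tiles with the smallest p, named after their values were seen, included 4 in Tnfrsf21, the death receptor DR6, the first at 62.0% and 89.0% on chromosome 17 from 43054001 to 43056000 (27.1 points, adjusted p = 2.42e-10, exact test). Both leading tiles of Ppard, a fatty acid nuclear receptor, rose, by 24.3 and 39.5 points. A tile of Stat5a, a transcription factor acting below cytokine receptors, rose from 42.4% to 67.3%. A tile of Casc3, a component of the exon junction complex, fell from 39.2% to 14.3%, and a tile of Gpatch8 fell from 75.3% to 38.0%. A tile of Grb10, an imprinted gene for a growth-signal adaptor, on chromosome 11 from 12026001 to 12028000 rose from 34.2% to 55.7% (21.5 points, adjusted p = 3.38e-10, exact test). Grb10 is also a member of the fixed heme-regulated kinase and ATF4 list, and its CpG-rich end lay at 4.04% and 3.16%.

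**Figure D3:**
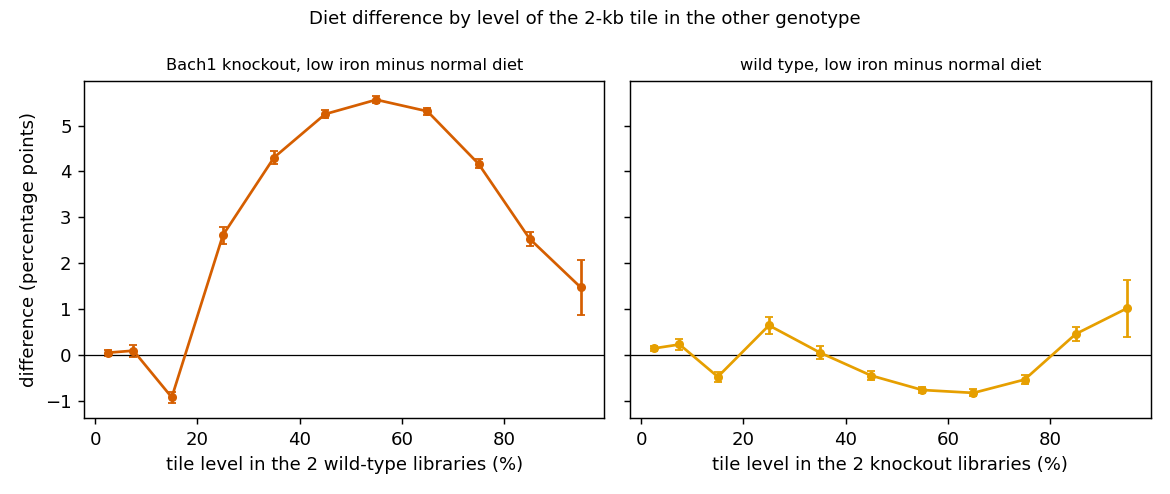
Diet difference in percentage points (vertical) against the level of the 2-kb tile in the 2 libraries of the other genotype (horizontal, percent), with 95% intervals. In the knockout the difference is 0.050 points for tiles under 5% and 5.56 points at 50 to 60%; in wild type it lies between -0.826 and 1.02 points.

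In this comparison 0 list members were called over all promoters or adjusted over the list alone, but several lists were barely measured. Iron handling had 1 measured promoter, that of Aco1 (4.97% and 3.18%), and the heme-regulated kinase and ATF4 list had 2. The 0 therefore says little about those lists. The globin list had a median of -8.65 points over 5 promoters, at the 0.095 percentile of random lists. Its members went both ways: the adult alpha globin genes Hba-a1 (21.5% to 11.8%) and Hba-a2 (26.8% to 14%) lay lower, as did Hbq1a (38.4% to 29.8%), and the embryonic Hba-x lay higher (71.1% to 79.7%, adjusted p = 0.0441, exact test, under the 20-point minimum). Hba-a1 and Hba-a2 are near-identical copies with 41 to 107 calls per library and are uncertain. Of the 5 globin genes, 2 were higher and 3 lower, and they lie close together on chromosome 11. The list therefore does not hold 5 separate observations. Medians were 0.273 points for heme synthesis (3 promoters, percentile 71.9), 0.775 for BACH1 and NRF2 targets (4, 78.6), 0.444 for erythroid factors (6, 70.5), -2.70 for methylation enzymes (3, 6.90) and -0.0589 for housekeeping promoters (3, 44.8); with 500 bp on each side heme synthesis stood at percentile 11.5 and erythroid factors at 34.4, and with 2 kb outside the end housekeeping promoters stood at 76.9. Myeloid promoters had a median of 12 points (3, percentile 97.4), including Csf1r, a growth factor receptor of macrophages (53.4% to 70%, adjusted p = 0.00342, exact test, under the minimum), and Csf3r (46.5% and 58.5%). The germline promoter of Dazl lay at 58.5% and 52.7%. Over whole gene spans, a region chosen after seeing the data, 9 erythroid genes had a median of 0.591 points, at the 1.68 percentile of random lists whose middle value was 3.24, with a mean of 1.43 and 6 higher and 3 lower. Tal1, an erythroid transcription factor, stood at -2.81 points and Slc4a1, the red cell anion exchanger, at -2.37, while Ermap, a red cell membrane protein, stood at 6.88 and Tmod1, a cap of the membrane skeleton, at 4.32. Spans of 3 genes of the methylation enzyme list had a median of -0.279 (percentile 2.30) but a mean of 1.06, 1 higher and 2 lower. These were Mbd1, Mbd2 and Uhrf1, so no Dnmt or Tet gene was measured in this comparison. The globin span value (-8.65, percentile 0) repeats the promoter value, because these short genes were taken whole in both. Random lists were matched on level but not on length or calls, so short windows with few calls can fall in their tails. Heme synthesis spans (3.58, 57.5), BACH1 and NRF2 target spans (1.72, 31.8) and housekeeping spans (1.08, 24.7) lay nearer the middle. Spans of 4 myeloid genes had a median of 7.88 points (percentile 99.6), with Mpo, myeloperoxidase, 8.12 points higher and Csf3r, a neutrophil growth factor receptor, 8.26 higher. Spans of 5 megakaryocyte genes had a median of 7.34 (98.1), with the platelet integrin Itga2b 9.26 points higher. Spans of B cell genes had a median of 5.70 (4, 89.9) and those of T and NK cell genes 2.11 (3, 19.4).

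**Figure D4:**
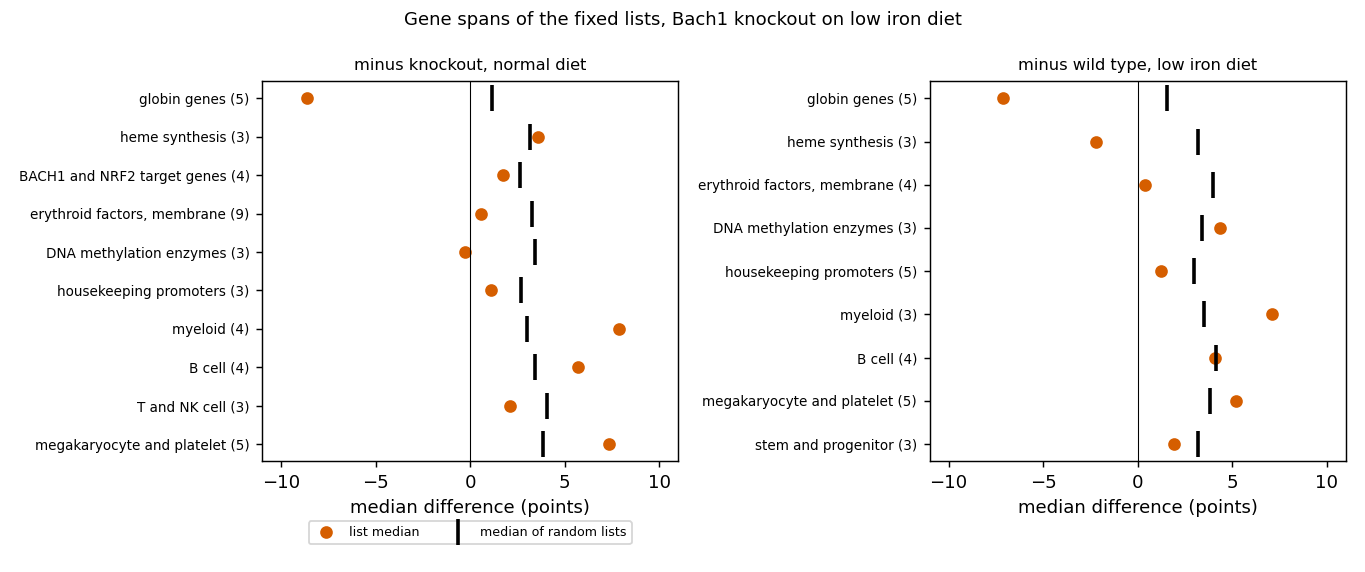
Median methylation difference in points over the gene spans of each fixed list with at least 3 measured genes (number in brackets), for the knockout low-iron library against the knockout normal-diet library (left) and the wild-type low-iron library (right); black marks are the medians of random lists matched on level. On the left, erythroid spans lie at 0.591 and myeloid spans at 7.88 points.

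The third comparison asks what the loss of BACH1 went with on the normal diet. The level was higher in the knockout library by 0.124 points on chromosomes 11 and 17 (95% interval 0.0859 to 0.162), but this direction did not hold: over all 7 shared chromosomes the difference was -0.115 points, with 2 higher and 5 lower, and over cytosines called in all 4 libraries it was -0.104 points. The promoters of Ankrd66, an ankyrin repeat gene (20.8% to 42.9%, adjusted p = 0.00188, Fisher's exact test), and Krt39, a hair keratin (36.2% to 57.3%), rose. That of Cdrt4 fell from 66.9% to 41.1% (adjusted p = 0.00350, exact test), and that of Fggy, a carbohydrate kinase on chromosome 4, rose from 14% to 34.3% (adjusted p = 0.000267, exact test). With 2 kb outside the end none of Ankrd66 (5.48 points), Cdrt4 (-18.5) and Fggy (11.7) was called, and with 500 bp on each side Ankrd66 (32.8) and Fggy (11.7) were not, while Krt39 was called in both. Of 2159 promoters, 6 were called, 4 higher and 2 lower. The 3 outside the naming rule, named after their values were seen, were olfactory receptor genes: Olfr20 rose from 9.62% to 55.4% (45.7 points, adjusted p = 0.000117, exact test), Olfr135 rose from 29.5% to 69.8%, and Olfr224 fell from 62.2% to 36.4%. Olfr20 had also been called higher in the wild-type low-iron library, at 40%, against the same wild-type normal-diet library, on 52 calls there. Of 93927 tiles 203 were called, 73 higher and 130 lower. On 1 strand, 260 and 265 tiles were called between these libraries, again fewer than between strands. Scaling by the inflation of the statistics left 4 tiles and 0 promoters. The tile with the smallest p in a named gene lay in Camk2b, a calmodulin-dependent kinase, and fell from 73.2% to 48.5% (adjusted p = 4.29e-10, exact test). A tile of Cdkl4 rose from 12.7% to 35.1% and a tile of Tenm2 from 21.2% to 48.9%; these were named after their values were seen.

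The globin promoters had a median difference of 4.17 points in this comparison over 10 genes (percentile 95.9), 6 higher and 4 lower and 0 called. Hbb-bh2 lay at 68.8% and 56.3% and Hba-a2 at 15.3% and 26.8%. The beta globin genes Hbb-bs (30.3% to 39.0%) and Hbb-bt (12.8% to 18.0%) rest on 47 to 82 calls per library. Medians were -0.227 points for heme synthesis (3 promoters, percentile 23.3), 1.17 for iron handling (8, 86.6), 0.239 for BACH1 and NRF2 targets (9, 30.3), 0.0914 for erythroid factors (8, 32.8) and -0.103 for the heme-regulated kinase and ATF4 list (6, 21.2). Slc48a1, the heme transporter, lay at 4.99% and 10.3% (adjusted p = 0.0144, exact test, under the 20-point minimum), and Mafg, a small MAF partner of BACH1, at 5.65% and 7.63%. The Slc48a1 level of 4.99% is the same wild-type normal-diet value as in the wild-type diet comparison, so the 2 differences are not separate observations. The myeloid promoters, whose median was lower in both comparisons, share that library as well. Their members were mixed, 2 higher and 3 lower in the wild-type diet comparison and 1 higher and 3 lower here. Among markers, the myeloid median was -5.23 points (4, 6.13), the B cell median -2.60 (3, 4.29), the megakaryocyte median -1.11 (5, 25.9) and the stem and progenitor median 0.575 (5, 82.5). With 2 kb outside the end the B cell list stood at percentile 79.3 and the stem and progenitor list at 12.7, and with 500 bp on each side heme synthesis stood at 87.8, iron handling at 30.6, BACH1 and NRF2 targets at 95.9 and erythroid factors at 72.8. Ly6g, a neutrophil surface protein, was the 1 list member called when adjusted over the list alone (47.7% to 27.0%, -20.6 points), and it was not called over all promoters (adjusted p = 0.0700, exact test). Itgam, an integrin of myeloid cells, lay at 47.6% and 39.3%, and Ppbp, a platelet chemokine, at 49.3% and 59.2%. Imprinted promoters had a median difference of -0.881 points (4, 29.4), with Zrsr1 at 55.1% and 53.1% Peg3 at 42.5% and 42.7%, and Zim1 at 21.8% and 16.2%. Germline promoters had a median difference of 0.275 points (4, 65.7), with Dazl at 47.5% and 58.5%, and housekeeping promoters 0.532 (7, 60.7).

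The fourth comparison asks what the loss of BACH1 went with on the low iron diet. Its knockout library is the same low-iron library as in the knockout diet comparison. Promoters, tiles and lists that differed in both comparisons are therefore not separate observations. The knockout library was higher by 4.45 points (95% interval 4.42 to 4.49) on chromosomes 11 and 17 and on 5 of 5 shared chromosomes (4.28 to 5.18), and higher in 364 of 364 windows of 500 kb. The Evi2 and Evi2a promoter window rose from 27.6% to 50% (22.4 points, adjusted p = 0.00362, Fisher's exact test); with 500 bp on each side it differed by 7.41 points and was not called. The same Grb10 tile rose from 27.2% to 55.7% (28.5 points, adjusted p = 3.07e-26, exact test). Other tiles named after their values were seen were one in Sgcd, delta-sarcoglycan (2.63% to 85.7%, on 38 and 49 calls), one in Ube2o, a ubiquitin enzyme of maturing red cells, which fell from 33.9% to 12.7%, and 3 in Gmpr, GMP reductase, on chromosome 13, of which the first rose from 54.6% to 86.3%. A tile of Dapk1, a death-associated kinase, fell from 45.0% to 17.3%. Of 2159 promoters, 4 were called, all 4 higher, again with the window of Evi2 and Evi2a counted for each gene. Olfr1388 (23.2 points) and Gm11677 (24.9) lie outside the naming rule and were named after their values were seen. Of 93927 tiles 1298 were called, 1230 higher and 68 lower. Against the median tile difference of 4.41 points, 703 were called, 391 higher and 312 lower, again evened out by the centring. Scaling by the inflation of the statistics, which again counts the shift as noise, left 3 tiles and 0 promoters.

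The globin promoters had a median of -7.12 points in this comparison (5 genes, percentile 0.175), with Hba-a2 at 33.3% and 14%, Hbq1b at 37.6% and 26.6%, and Hba-x at 69.4% and 79.7%; with windows of 500 bp each side the percentile was 9.57. Medians were -0.906 points for heme synthesis (3, 9.21), 0.0537 for erythroid factors (3, 38.5, with a mean of -8.14), 1.5 for methylation enzymes (3, 73.3), 0.0636 for housekeeping promoters (5, 47.1) and 0.534 for stem and progenitor markers (3, 64.5), and 0 members were called over all promoters or adjusted over the list alone. Only 2 iron handling promoters, 2 of BACH1 and NRF2 targets and 1 of the heme-regulated kinase and ATF4 list were measured here. Stem and progenitor markers stood at percentile 1.98 with 500 bp on each side, and methylation enzymes at 24.1 with 2 kb outside the end. The erythroid mean differs from its median because of Rhag, a red cell membrane protein, at 95% and 70% on 20 and 50 calls (-25 points, adjusted p = 0.195, exact test). The myeloid gene Csf1r lay 14.1 points higher (adjusted p = 0.0154, exact test) and the germ cell gene Dazl at 59.7% and 52.7% (adjusted p = 0.0428, exact test), both under the 20-point minimum. Over whole gene spans, erythroid genes had a median of 0.410 points (4 genes, percentile 2.73), 2 higher and 2 lower. Heme synthesis genes had a median of -2.18 (3, 1.52) and a mean of -0.586, with Fech, the last enzyme of heme synthesis, at -3.44 points, Tmem14c at -2.18 and Cpox, an enzyme of the pathway, at 3.86. Random lists had middle values of 4.01 and 3.22 points. Spans of the methylation enzyme list, again Mbd1, Mbd2 and Uhrf1, had a median of 4.36 (3, 70.2), against -0.279 in the knockout diet comparison. Housekeeping spans had one of 1.22 (5, 16.4). Myeloid spans had a median of 7.13 (3, 96.9), megakaryocyte spans 5.20 (5, 78.1), B cell spans 4.11 (4, 48.8) and stem and progenitor spans 1.92 (3, 29.3).

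The last comparison set the diet differences of the genotypes against each other. The diet difference was 3.96 points in the knockout and -0.370 points in wild type, so they differed by 4.33 points (95% interval 4.28 to 4.38). Of 93927 tiles, 982 had a difference of diet differences past the test, 895 higher in the knockout and 87 lower, and 15668 had an unadjusted p under 0.05. The median over tiles was 5.23 points, so the shift of the whole library enters these counts and their direction. Tiles were not tested against this median, so how many hold a local difference stays open. In the Grb10 tile the level was 40.04% and 27.2% in wild type on the normal and low iron diets and 34.2% and 55.7% in the knockout, a difference of diet differences of 34.3 points. Of 2159 promoters, 4 were called: those of the olfactory receptor genes Olfr224 (32.3 points) and Olfr139 (31.9) and of 4930564C03Rik (30.3) were higher, and that of Tgtp2 lower (-37.3). The naming rule covers the 4 pairwise comparisons, so these 4 were named here after their values were seen; Tgtp2 was also named by the rule in the knockout diet comparison, where its call depended on the window. Scaling by the inflation of the statistics left 4 tiles and 0 promoters. Across 500-kb windows, which are not independent replicates, the diet differences of the genotypes had a correlation of -0.386, and across 2-kb tiles one of -0.0132.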

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

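All tests of explanations in this part were chosen only after the results were seen. The setting without the deepest cytosines was itself planned, but not its use as such a test.

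The diet difference of the methylation level differed between the genotypes by 4.33 points on chromosomes 11 and 17, and it was brought up because its interval (4.28 to 4.38) excludes 0. The same test of the difference itself brought up 982 tiles and 4 promoters. It was not made against the median tile difference of 5.23 points, so the shift of the whole library enters the count of tiles. With z scaled by the inflation of its own statistics, 4 tiles and 0 promoters were left. Calls on chromosome Y in the knockout normal-diet library numbered 27245, and calls on 5 unplaced contigs in the wild-type low-iron library numbered 21903; both were brought up because they lie outside the chromosomes compared, and no other library was analysed there.

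The first pattern is the higher level in the knockout low-iron library. Incomplete bisulfite conversion would add most where methylation is lowest, and tiles under 5% methylated in wild type differed by only 0.050 points (-0.0120 to 0.112), which argues against it. Without the deepest cytosines the difference was 4.13 points, which argues against a few very deep sites. An admixture of myeloid cells, which the sort on CD71 and Ter119 would remove, would keep myeloid genes from rising beyond other genes; their median rise stood at the 99.6 percentile of random lists against the knockout normal-diet library (4 spans), itself low for these genes (1.58 against wild type), and at 96.9 against the wild-type low-iron library (3 spans), too few genes and too close to the bound to exclude it. Both of these comparisons share the knockout low-iron library, so they are not separate observations. A difference in the maturity of the sorted cells, variation between animals or libraries, and a response to low iron without BACH1 may each be involved, and none was tested with 1 library per group.

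The second pattern is the number of tiles called. In the wild-type diet and normal-diet genotype comparisons, 250 to 265 tiles were called on 1 strand, against at least 547 between the strands of a single library. Calls that are not independent within a tile may account for these counts. The strand comparison cannot settle this, because it exceeds the counts between libraries and so holds more than such dependence. Simulated tiles without change gave 69 calls in the normal-diet genotype comparison with calls correlated at an inflation of 1.61, below the 203 observed on both strands. How much of the counts such dependence accounts for stays open. For the comparisons with the knockout low-iron library, 934 to 1083 tiles were called on 1 strand, above the highest count between strands of 693, which argues against dependence of calls as the explanation for the whole excess. That library was shifted as a whole, higher in 363 of 364 windows of 500 kb in the diet comparison and in 364 of 364 in the genotype comparison. Against the median tile difference, 737 and 703 tiles were called there. The wild-type diet and normal-diet genotype comparisons gave 397 and 338 in that setting. How much of the excess is local stays open.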

How the results depend on the processing

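Alternatives using shared chromosomes (other windows for promoters named there included) or the inflation between strands were chosen after seeing the data; the others were planned. In each group of values the order is wild-type diet, knockout diet, genotype on normal diet and genotype on low iron diet, and the cause of each change was not tested unless the alternative's construction gives it.

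The level difference was -0.409, 4.08, -0.104 and 4.39 points over cytosines called in all 4 libraries, -0.212, 3.92, 0.387 and 4.52 as the mean of levels of cytosines with at least 5 calls, and -0.287, 3.81, 0.568 and 4.66 as pooled calls of those cytosines. Without the deepest cytosines the first 3 were -0.327, 4.13 and -0.0129 points, and over shared chromosomes all 4 were -0.562, 4.20, -0.115 and 4.70. The normal-diet genotype difference therefore reversed in 3 of its 5 alternatives, and the other comparisons kept their direction in all of theirs.

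Tiles called numbered 82, 368, 64 and 339 at a minimum of 30 points, which by construction is stricter. They numbered 397, 737, 338 and 703 against the median difference, 3, 6, 4 and 3 with z scaled by its own inflation, 0, 30, 2 and 14 with the inflation between strands, and 2, 53, 5 and 45 with that inflation against the median difference. With 1-kb tiles the wild-type diet and normal-diet genotype comparisons gave 360 and 313, with 5-kb tiles the 4 gave 69, 486, 67 and 507, and shared chromosomes, which hold more tiles, gave 884, 2974, 779 and 3118.

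Promoters called numbered 1, 2, 2 and 0 at 30 points, 0, 0, 0 and 0 with z scaled by its own inflation, 0, 0, 1 and 0 with the inflation between strands, and 0, 0, 1 and 0 with that inflation against the median difference. Windows of 500 bp on each side gave 5 in the wild-type diet and 7 in the low-iron genotype comparison, windows of 2 kb outside the end gave 7 and 26, and shared chromosomes gave 12 for the wild-type diet. For the difference of diet differences, a minimum of 40 points left 405 tiles and 0 promoters, and scaling by the inflation left 4 tiles and 0 promoters.

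Against random lists not matched on level, percentiles were 0.485 for myeloid promoters in the wild-type diet comparison, 99.6 in the knockout diet comparison and 1 in the normal-diet genotype comparison, and 99.7 for globin promoters in the last. With 500-bp windows they were 99.3 for myeloid promoters in the knockout diet comparison, and 9.57 for globin and 1.98 for stem and progenitor promoters in the low-iron genotype comparison. With 2 kb outside the end, methylation enzymes in the knockout diet comparison were at 0.52.

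Of 109 alternatives for list percentiles, 7 moved into and 1 moved out of the outer 5% of random lists, but 28 moved to the other side of percentile 50, 12 of 38 with 500-bp windows, 12 of 32 with 2 kb outside the end and 4 of 39 without matching on level. Stem and progenitor promoters in the low-iron genotype comparison moved from 64.5 to 1.98. With 500-bp windows erythroid promoters in the wild-type diet comparison moved from 4.72 to 71.1, and with 2 kb outside the end B cell promoters in the normal-diet genotype comparison moved from 4.29 to 79.3. Of 48 alternatives for tiles 18 stayed within 1.5 times, of 44 for promoter counts 23 did, and of 131 for named promoters 59 kept the call, 72 lost it and 0 reversed. Windows around BACH1 motifs were not run. No paired analysis was possible because each group holds 1 library. Depth and the 20-point minimum both limit the tile test. At the depths of the normal-diet libraries, 26.5% of simulated changes of 20 points passed the adjusted p. With the minimum as well, 19.5% were recovered. These calls were drawn as independent, and recovery with correlated calls was not simulated. Smaller changes were not simulated and are left out by the 20-point minimum; on the adjusted p alone 448 tiles passed in the wild-type diet and 3671 in the knockout diet comparison, against 236 and 1489 called.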

Other observations

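All tests of explanations in this part, and the use of whole gene spans, were chosen only after the results were seen.

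Over whole gene spans, 12 iron handling genes had a median difference of 1.87 points in the wild-type diet comparison, at the 96.8 percentile of random lists, with 9 higher and 3 lower and 0 called. Tfrc, the transferrin receptor, lay at 37.1% on the normal and 44.5% on the low iron diet, Snx3, which helps recycle that receptor, at 40.8% and 47.2%, and Pcbp2, an iron chaperone, at 53.6% and 60.3%; all 3 were under the 20-point minimum. Spans of 7 methylation enzyme genes were lower in 7 of 7 (median -2.10 points, percentile 5.43), including Mbd3, a subunit of a chromatin remodelling complex, at 41.0% and 34.2%, again with 0 called. Myeloid spans had a median of -2.39 points there (8 genes, percentile 1.05), 2 higher and 6 lower. Erythroid spans went the other way, with a median of 1.70 (10, 94.4), 7 higher and 3 lower. In the normal-diet genotype comparison, against the same wild-type normal-diet library, myeloid spans had a median of -3.11 points (5, 1.58) and megakaryocyte spans -1.68 (8, 4.27), with Itga2b at 47.5% in wild type and 42.4% in the knockout. Globin spans, which are the promoter windows again, had a median of 4.17 (10, 99.8), 6 higher and 4 lower. The same median stood at percentile 95.9 among promoters. Random spans were matched on level but not on length or calls, so the percentile of these short genes among spans says little. Housekeeping spans were higher in 9 of 9 (median 2.60, percentile 89.1). On the chromosomes analysed in every library, the knockout normal-diet library held fewer promoter calls than the wild-type one (874445 against 1024098). Span levels pool all calls, so fewer calls in promoters of low methylation could raise them without a change at single cytosines. This was not tested.

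The promoter of Dazl, a germ cell gene that is methylated in most other cells, lay at 47.5% in the wild-type normal-diet library, 59.7% in the wild-type low-iron library, 58.5% in the knockout normal-diet library and 52.7% in the knockout low-iron library. A tile overlapping Hic2 and Tmem191c on chromosome 16 (17260001 to 17262000) lay at 32.8% in the wild-type normal-diet library and 84.2% in the wild-type low-iron library (adjusted p = 1.61e-08, exact test), and was named after its values were seen. Larger windows average out more counting noise. The correlation of strand differences across windows, which are not independent replicates, was 0.0457 over 2 kb and 0.662 over 500 kb in the knockout diet comparison, and 0.00755 and 0.396 in the wild-type diet comparison, while the spread shared by the strands was smaller in larger windows, 2.29 and 1.26 points (SD) in the former and 0.951 and 0.736 in the latter.

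The third pattern is the change inside Bach1 in the knockout low-iron library. Of the 20 leading tiles of chromosome 16, 3 lay inside this gene, the target by design, at 2 separate places, since adjacent tiles count once; 0 of 47501 windows of its length elsewhere held as many, which argues against chance placement. These windows overlap, in steps of 2000 bp, so they are not separate trials and their number overstates the strength of this argument. Well-covered cytosines without calls in that library made up 2.25% (1.77 to 2.87) of those within 1 Mb of the gene, outside it, against 0.980% on the rest of the chromosome, but neighbouring cytosines share reads, the interval treats them as independent, and 3 of 45 other windows of 2 Mb reached this share (highest 3.30%); without the leading stretches, which include 17 and 12 cytosines at 82 and 87.6 kb from the gene, it was 1.98%, reached by 5 windows. Cytosines at least 90% methylated in wild type and 0% in that library made up 1.23% of this flank (3 of 244) against 0.0693% elsewhere, above all of 38 windows, but these 3 lay at 1 place, so whether sequence of another mouse strain was carried along with the targeted gene, whose strain is not given in the sources used here, stays open. An altered allele itself may account for the uncovered 239 bp and was not tested against sequence.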
